A study of Macaca mulatta with 9 samples.

How the data were processed

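The samples were small antral follicles (SAFs) of rhesus macaques, collected at or near menses per the labels. SAFs presumed healthy by their clear antrum were pooled by female and ovary, 3.7 ± 0.3 SAFs per ovary from 3 ovaries per group (the kind of error is not stated), and lysed with their whole cellular content. Per the labels, total RNA was amplified with a NuGEN 3' IVT protocol and hybridised with biotin label to 1-colour Affymetrix arrays, 1 array for each of 9 samples. The deposited values are linear signal intensities per probe set, made with MAS5 according to the submitters' processing notes, which give no version. On all 9 arrays the mean without the lowest and highest 2% of probe sets was 200.01, so the authors had scaled each array to 1 common trimmed mean. Median signals were 20.6, 22.3 and 23.8 for control replicates 1 to 3, 21.4, 19.7 and 15.9 for WSD, and 21.7, 23.5 and 22.1 for WSD+T. MAS5's detection calls and its other settings were not used here and stay unknown, as does any step before the scaling. The genome build was not given in the sources used here. For arrays, their number limits the precision.

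The table held 52865 probe sets, of which 99 were controls and were left out of all tests. Symbols came from the array's annotation: 24969 probe sets had 1 symbol, 361 had several and 27535 were not listed. Of those with 1 symbol, 24629 had an Entrez ID found in a RefSeq table of a rhesus macaque assembly, used only to check names, and none of these had a different symbol there. Among the tested probe sets, 16625 had 1 symbol and stood for 10002 genes, 219 had several and 9539 had none. Some probe sets of 1 gene may measure different transcripts, and the annotation was not checked against probe sequences.

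Values were analysed as log2 of signal plus 16, which understates fold changes of genes with low signal. A probe set was tested if its mean over the 9 arrays was at or above the median of all non-control probe sets (5.22 on this scale, a signal of about 21.2), which left 26383. One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom and a prior of 2.69), without further normalization. The 3 pairwise comparisons and an F test over the groups were adjusted separately by Benjamini-Hochberg, with a threshold of 0.05. Groups were taken from the labels, and the 3 replicates of a group are labelled as biological replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

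Lists of 22 gene groups and 12 cell types were fixed from general knowledge, and 32 of them had at least 5 tested genes. Each gene was represented by its tested probe set with the highest mean. Lists were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with the correlation estimated from the data and limma's fry beside it. Camera compares a list with other genes, whereas fry tests whether its genes move on balance in 1 direction. A list's score on an array is the mean of its genes' log2 values, each centred on its mean over the arrays. Groups, tests, thresholds, lists, the rule for named genes and most other settings tried were chosen before the data were examined. That rule took up to 12 higher and 12 lower genes past the threshold by size of change, with the probe set of smallest p per gene, up to 4 genes per list by smallest p, and a fixed set of genes whatever their p, among them FSHR, LHCGR, ESR1, ESR2, INSR, STAR, CYP17A1, CYP19A1, HSD3B2 and AMH. Other genes named as the only called members of a list were chosen after their values were seen.

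The covariance of the fold changes of WSD and of WSD+T against the shared control arrays was compared with simulated data in which only those arrays linked the comparisons. The overlap of calls between comparisons that share a group was set beside 20 simulations with no change in any group. Each probe set had its own residual SD, the same in every group. In both kinds of simulation the probe sets varied independently. As many probe sets per direction were taken by smallest p as were called in the data, which matches ranks and not calls. The replicate numbers were checked for pairing of samples by the correlation of residuals.

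The pipeline was tested on simulated data with the same number of arrays, where 50 probe sets were changed at each of 4 sizes. At 1.5-fold, 2-fold, 4-fold and 8-fold it recovered 2, 17, 41 and 46 of 50 in WSD vs control, with 3 false calls of 109. In WSD+T vs control it recovered 2, 15, 43 and 46, with 8 false calls of 114, and in WSD+T vs WSD 0, 12, 43 and 45, with 7 of 107. Camera called a list raised 2-fold in 20 of 20 simulations and no unchanged list, over 10002 genes. The simulated genes varied independently, so false calls of lists whose genes vary together could not appear there. Each simulated probe set also had 1 SD in all groups, and the arrays were independent, as the fitted model assumes. The real groups differed in mean within-group variance (0.330 in WSD, 0.152 in control and 0.0411 in WSD+T). The numbers of recovered and false calls therefore need not hold for the real comparisons.

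The other settings chosen at that time were pseudocounts of 1 and 64, no filter and a filter at the upper quartile, quantile normalization, median centring and cyclic loess, variance trends with and without robust estimation, array weights, fits to 2 groups only, 1 probe set per gene, the replicate number as a block, 3'/5' ratios of actin and GAPDH as covariates for the counts of probe sets, and leaving out each array. Chosen after seeing the data were array weights per group and gene by gene, WSD+T replicates 1 and 3 averaged into 1 sample, the mean of the myeloid markers as a covariate, and the 3'/5' ratios as covariates for the list tests.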

Results

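Expression was measured on 1-colour Affymetrix rhesus macaque arrays in small antral follicles (SAFs), ovarian follicles that have formed a fluid-filled antrum, from young adult females in the early follicular phase. There were 9 arrays in 3 groups of 3 biological replicates: control females on a standard diet, females on a Western-style diet (WSD), and females on that diet with chronic testosterone (WSD+T). Each sample held the whole cellular content of SAFs pooled per female and ovary, 3.7 ± 0.3 per ovary per the labels, so granulosa cells, the follicle wall and the cumulus-oocyte complex were measured together. The median signal per array ran from 15.9 (WSD replicate 3) to 23.8 (control replicate 3), and the mean without the outer 2% was 200.01 on every array to 2 decimals. The number of arrays limits the precision. Fold changes are on the log2 scale, group signals are means ± SD of n = 3 arrays, and adjusted p values are from limma, or from camera for gene lists, over all 26383 tested probe sets or 32 tested lists. The ranges over the alternatives given for lists also include fry, which does not compare a list with other genes.

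The comparison of WSD with control asks what the diet did to the SAF transcriptome. Of the 24 tested genes of the proliferation list, 15 were called lower after the diet and none higher. The list passed camera at the preset correlation (adjusted p = 1.75e-07) but not with an estimated one (adjusted p = 0.446). The proliferation marker MKI67 fell from 539 ± 171 to 103 ± 22.3 (log2 fold change -2.20, SE 0.23, adjusted p = 0.00296). The replicative helicase subunit MCM3 fell from 1570.1 ± 88.1 to 563 ± 71.0, and the spindle factor TPX2 from 812 ± 112 to 277 ± 49.2. The inhibin beta-B subunit INHBB fell from 138 ± 27.5 to 16.1 ± 12.5, and the inhibin alpha subunit INHA also fell (-2.09, adjusted p = 0.0173), but did not pass without control replicate 3 (0.0620, lowest of the leave-one-out fits 0.00731). The proteoglycan lumican, LUM, had the greatest decrease among named genes, from 695 ± 256 to 21.5 ± 11.3 (-4.22, SE 0.40, adjusted p = 0.00296). The calcium-responsive transcription factor NFATC2 rose from 102 ± 43.0 to 2045 ± 461 (4.16, SE 0.40, adjusted p = 0.00296), and CHAC1, a glutathione-degrading enzyme of the unfolded protein response, from 9.11 ± 7.65 to 292 ± 151.

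Other genes with a large increase after WSD included SLC7A11 (3.25, SE 0.64, adjusted p = 0.0147), a cystine transporter subunit, the muscle-type tropomyosin TPM2 (3.00, SE 0.49, adjusted p = 0.00842) and the parathyroid hormone-related peptide gene PTHLH (2.94, SE 0.47, adjusted p = 0.00758). The carbonic anhydrase CA13 rose too (2.84). Single genes with roles in the matrix also rose, the collagenase MMP1 (2.95), the stromelysin MMP3 (2.56), the hyaluronan synthase HAS2 (2.80) and the hyaluronan-binding protein TNFAIP6 (2.70), whose signal went from 109.8 ± 93.7 to 699.9 ± 239. The extracellular matrix and remodelling list did not pass. Of its 37 genes, 1 rose and 4 fell (median -0.04, camera's adjusted p = 0.959). The cytokine receptor TNFRSF12A rose from 171 ± 114 to 1031 ± 155, and the zinc finger gene ZNF655 rose (2.70). The remaining large decreases were in EFNB1 (-2.59), ST6GAL2 (-2.57), PAGE1 (-2.45), MAP6D1 (-2.39), UPK1B (-2.25), PLEKHH1 (-2.20), the endothelial selectin SELE (-2.18), the Wnt modulator DKK2 (-2.18) and the signalling ligand IHH (-2.28), whose receptor PTCH1 also fell (-1.96). The mean signals of SLC7A11, MMP3 and CHAC1 in control, and of INHBB, IHH and SELE in WSD, were under the filter's signal of 21.2, as were those of AREG and STAT3, named below, in control. Their fold changes thus depend on the pseudocount. Of these 24 genes with the largest changes, 18 passed in every fit that left out 1 array and kept the gene above the filter. Without control replicate 3, HAS2, MMP1, SELE and SLC7A11 did not pass (adjusted p = 0.110, 0.132, 0.0535 and 0.0510, each the highest of the leave-one-out fits, whose lowest were 0.0254, 0.00758, 0.0134 and 0.00778). Without control replicate 2, MAP6D1 and PAGE1 did not pass (adjusted p = 0.122 and 0.122, lowest of the fits 0.0213 and 0.0215). MMP1 passed in only 1 of the 9 fits, without control replicate 1, PAGE1 in 2, without WSD replicate 1 or WSD+T replicate 2, and MAP6D1 in 4, without control replicate 3, WSD replicate 3 or WSD+T replicate 1 or 2. HAS2 also missed it without control replicate 2, WSD replicate 1 or WSD+T replicate 1 (0.0792, 0.101 and 0.0599).

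Within the lists fixed beforehand, proliferation had the smallest p and the most genes called: 15 of 24 tested genes fell, none rose and 9 did not pass, with 17 lower when adjusted over the list alone (median -0.89; camera's adjusted p = 1.75e-07, adjusted p = 0.446 with an estimated correlation, range over the alternatives 2.23e-09 to 0.446). Its mean score, a centred log2 value, was 0.59 ± 0.18 in control and -0.27 ± 0.12 in WSD. Genes of the ovulatory response rose, 6 of 18 over all genes and 9 adjusted over the list alone (median 0.54, camera's adjusted p = 0.00153, adjusted p = 0.446 with an estimated correlation, range over the alternatives 3.83e-05 to 0.446). They included the EGF-like ligand AREG (2.26), the transcription factor RUNX1 (1.00) and the protease CTSL (1.44). The unfolded protein response list was higher, with 4 genes up, 1 down and 13 not past the threshold out of 18, and 6 up and 1 down adjusted over the list alone (median 0.21, camera's adjusted p = 0.00592, adjusted p = 0.529 with an estimated correlation, range over the alternatives 0.000443 to 0.529). The risen genes were CHAC1, the asparagine synthetase ASNS (1.92), the transcription factor XBP1 (0.74) and HERPUD1 (1.07), and EDEM1 fell (-0.48, adjusted p = 0.0367).

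Insulin and IGF signalling passed as higher, with 4 of 33 genes up and 2 down, or 5 up and 2 down adjusted over the list alone (median 0.11, camera's adjusted p = 0.0225, adjusted p = 0.446 with an estimated correlation). Over the alternatives its adjusted p ranged from 0.00510, given by fry, to 0.446, given by camera with an estimated correlation. Its examples were the insulin-receptor phosphatase PTPN1 (1.12), the adaptor SHC1 (0.57), the IGF-binding protein IGFBP6 (1.25) and the mTOR inhibitor TSC1 (-0.97). Apoptosis and atresia had 3 of 17 genes up in either adjustment (median 0.46, camera's adjusted p = 0.0116, adjusted p = 0.446 with an estimated correlation, range over the alternatives 0.00140 to 0.446): the cell cycle inhibitor CDKN1A (1.61) and the pro-apoptotic genes BAK1 (0.98) and DIABLO (0.49). Inflammatory cytokines and NF-kB had 4 up and 2 down of 22, 5 up and 2 down adjusted over the list alone (median 0.56, camera's adjusted p = 0.0274, adjusted p = 0.832 with an estimated correlation, range over the alternatives 0.00149 to 0.832), among them RELB (1.39), STAT3 (1.34) and NFKB2 (-1.26). The interferon response had 1 of 25 genes up in either adjustment, the GTPase GBP1 (1.54), with a median of 0.29 (camera's adjusted p = 0.00592, adjusted p = 0.788 with an estimated correlation, range over the alternatives 6.12e-05 to 0.788). Macrophage and myeloid markers had a median of 1.12 with none of 13 genes called in either adjustment and 13 not past limma's threshold (camera's adjusted p = 0.0274, adjusted p = 0.885 with an estimated correlation, range over the alternatives 2.91e-06 to 0.885). The mean myeloid score was 0.82 and 1.73 on WSD replicates 1 and 2, -2.27 on WSD replicate 3, and 0.16, -1.62 and -1.46 on the control arrays, so the apoptosis, inflammatory and interferon lists were measured on arrays that also differed in myeloid markers. With the myeloid score as a covariate, chosen after the data were seen, these 4 lists did not pass (adjusted p = 0.0838, 0.284, 0.143 and 0.593). For the macrophage and myeloid list this was fixed in advance, since the covariate is its own mean.

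Single arrays decided several of these calls. Without WSD replicate 2 the apoptosis, interferon, inflammatory and macrophage lists had adjusted p = 0.0716, 0.158, 0.226 and 0.444, and without WSD replicate 3 insulin and IGF signalling had 0.0863. The inflammatory list also did not pass without control replicate 2 (0.283) or WSD replicate 1 (0.0632). The macrophage list did not pass without control replicate 2 (0.113), control replicate 3 (0.123) or WSD replicate 1 (0.224). Under median centring and cyclic loess, the inflammatory list had adjusted p = 0.0644 and 0.0526, and the macrophage list 0.0644 and 0.0835, as well as 0.0650 with a pseudocount of 1.

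The other 24 lists did not pass camera's threshold, with adjusted p from 0.0945 to 0.959. Since 14.5% of all tested probe sets were called, a few called genes do not show a change of such a list. In steroidogenesis, 3 of 20 genes fell in either adjustment (camera's adjusted p = 0.341, fry's adjusted p = 0.0130): the androgen-producing enzyme CYP17A1 (-1.67, SE 0.26, adjusted p = 0.00715), HSD3B2 (-1.04, SE 0.16, adjusted p = 0.00683), which converts pregnenolone to progesterone, and HSD17B8 (-0.60). All 4 called antioxidant genes rose, SRXN1 (1.27), MT2A (1.24), GCLM (0.70) and SOD2 (1.08), in a list with adjusted p = 0.347. TGF-beta family ligands and signalling had 4 genes up and 4 down, a median of -0.07 and a camera direction of up (adjusted p = 0.959). Examples were FSTL3 (1.18), SMAD4 (-0.71) and ID3 (-1.01). Basement membrane genes HSPG2 (-1.46) and LAMA1 (-1.71) and the proteoglycan BGN (-1.06) fell within the extracellular matrix list. The lipid genes FADS2 (-1.15), ACACA (-1.07), DHCR7 (-0.92) and SQLE (-1.03) fell. The androgen-induced list had PMEPA1 up (1.52) and NCAPD3 (-0.81) and CENPN (-0.78) down. Immediate early and heat shock genes FOS (-2.11), DNAJB1 (-1.39) and HSPH1 (-0.68) fell. Hormone receptors and the angiogenesis list had no gene called in any comparison (camera's adjusted p = 0.606 and 0.656 here). The median, the mean and camera's direction also differed in sign for hormone receptors, glycolysis and antioxidant defence, lists that did not pass.

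In limma, 3817 of 26383 probe sets passed (1262 higher, 2555 lower), or 1961 genes, of which 17 had probe sets in both directions, and 1693 of the probe sets changed at least 2-fold. The lower share was 66.9%, and it was 56.8% under quantile normalization (1498 higher, 1967 lower), 52.0% under median centring (1548 and 1679) and 50.3% under cyclic loess (1714 and 1737). Of all tested probe sets, 8124 (30.8%) had groups that did not overlap, against 10% by chance, as did 3808 of the 3817 called. In each comparison a small p nearly implies this for called probe sets, so it adds no support. The 10% is a mean over splits of the arrays, and with probe sets that vary together a single split can lie far from it. The count was 1735 without control replicate 2, 2048 without control replicate 3, 6628 without WSD replicate 3, 2463 without WSD+T replicate 1 and 2474 without WSD+T replicate 3. A fit to the 6 control and WSD arrays alone, with fewer samples, called 913, and 2536 were called with WSD+T replicates 1 and 3 averaged. Array weights per group, chosen after the data were seen, gave 1367. The main fit's 1 spread per probe set included the WSD+T arrays, whose mean within-group variance was 0.0411, against 0.330 in WSD and 0.152 in control. That spread was thus on average below that of the arrays compared here. The count of 3817 and the adjusted p values of this comparison depend on it and may be too favourable.

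**Figure D1:**
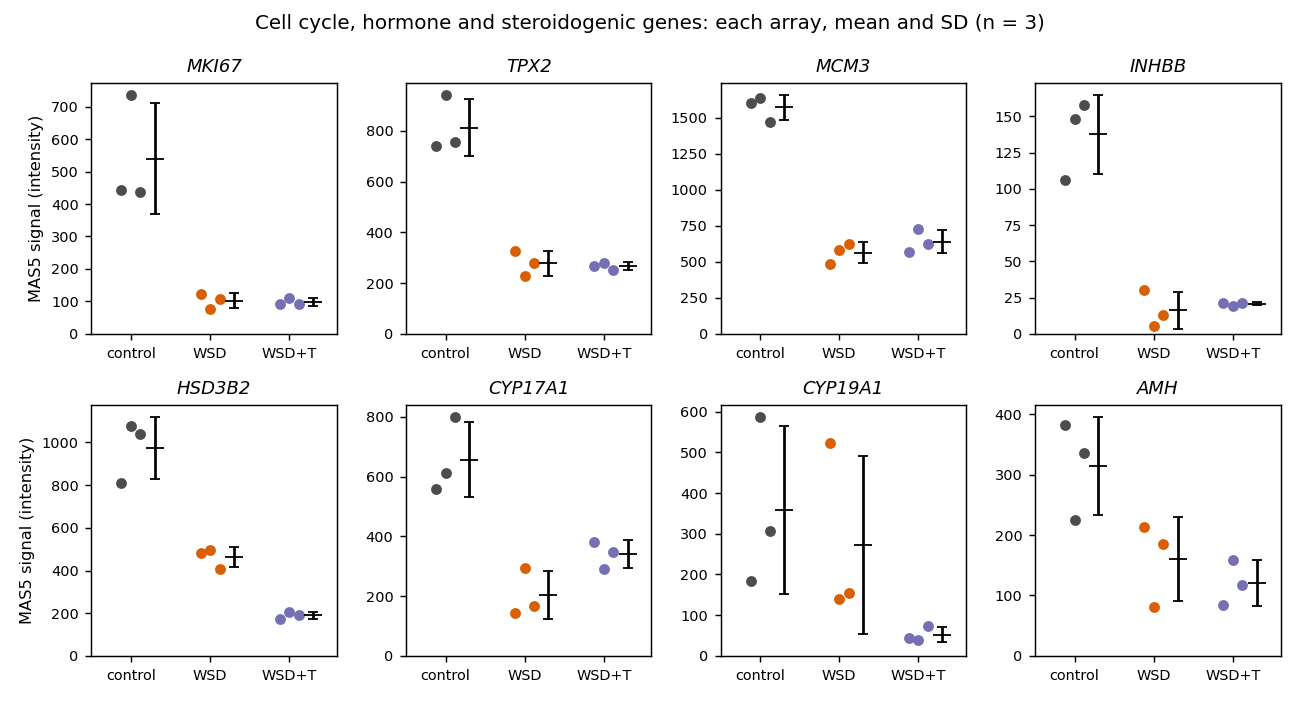
Signal (MAS5 intensity, linear axis) of 8 cell cycle, hormone and steroidogenic genes on the 9 arrays, by group. Points are single arrays and bars show the group mean ± SD: MKI67 was 539 ± 171 in control, 103 ± 22.3 in WSD and 98.0 ± 11.01 in WSD+T, and HSD3B2 was 976 ± 145, 463 ± 48.0 and 191 ± 17.3.

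The comparison of WSD+T with control asks what the diet and testosterone did together. HSD3B2 fell from 976 ± 145 to 191 ± 17.3 (log2 fold change -2.26, SE 0.16, adjusted p = 0.00642). Both inhibin subunits fell, INHA from 2032 ± 932 to 339 ± 56.8 and INHBB from 138 ± 27.5 to 20.7 ± 1.08, and MKI67 fell from 539 ± 171 to 98.0 ± 11.01. The cytokine oncostatin M, OSM, rose from 4.42 ± 3.66, under the filter's signal of 21.2, to 121 ± 30.0 (2.74, SE 0.21, adjusted p = 0.00642), and the matrix glycoprotein tenascin-C, TNC, from 76.0 ± 44.1 to 421 ± 100.1.

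The single genes IHH (-1.93), PTCH1 (-1.54) and HHIP, a hedgehog-binding protein (-1.90), fell, and neither of HHIP's 2 other tested probe sets was called. Leaving out 1 array, IHH passed in 3 of 7 fits (highest adjusted p = 0.172, lowest 0.0236) and HHIP in 3 of 9 (0.202 and 0.0309). ESM1, a proteoglycan secreted by endothelial cells, fell from 482 ± 82.2 to 107 ± 14.8, and the lipid transfer protein MTTP (-1.96), the chaperone DNAJB1 (-2.28), the heat shock factor HSF4 (-2.12, SE 0.22, adjusted p = 0.0139), TRMT2B (-2.19) and SPATA17 (-1.97) fell too. Increases were found in PKIA, an inhibitor of protein kinase A (2.89), S100A2 (2.82), the calcium-binding protein PVALB (2.65), the steroid-metabolising enzyme CYP3A5 (2.57), and NHLH2 (2.37, SE 0.21, adjusted p = 0.00980), a transcription factor. Other increases were in the tryptophan dioxygenase TDO2 (2.30), UBD (2.14) and the ubiquitin ligase subunit FBXO32 (2.09). MBLAC2 (3.80) and MLANA (3.59) also rose. In control the mean signals of MBLAC2, PVALB, NHLH2, UBD and OSM, and in WSD+T those of IHH, INHBB, MTTP and SPATA17, were under 21.2, and their fold changes depend on the pseudocount. For MBLAC2, 1 of 4 other tested probe sets had the same direction and none of them was called, and for MLANA 1 of 2 others had the same direction and was called.

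Proliferation was the list with the smallest p: 11 of 24 genes fell, none rose and 13 did not pass, with 20 lower adjusted over the list alone (median -1.02; camera's adjusted p = 3.47e-15, adjusted p = 0.198 with an estimated correlation, range over the alternatives 1.66e-17 to 0.198). Examples were TPX2 (-1.54), MCM3 (-1.28) and MCM2 (-1.11), and the list score was -0.32 ± 0.14 against 0.59 ± 0.18 in control. Steroidogenesis passed as lower, with 1 of 20 genes called, HSD3B2, and 4 lower adjusted over the list alone (median -0.33, camera's adjusted p = 0.0215, adjusted p = 0.304 with an estimated correlation, range over the alternatives 0.00524 to 0.304). CYP17A1 was 340.3 ± 46.3 in WSD+T against 657 ± 127 in control (adjusted p = 0.116), and the aromatase CYP19A1, which makes oestrogen from androgen, 52.0 ± 19.2 against 359 ± 206 (adjusted p = 0.0650). The granulosa cell list passed as lower with 2 of 17 genes down, INHA and INHBB, and 1 up and 4 down adjusted over the list alone (median -0.35, camera's adjusted p = 0.0314, adjusted p = 0.496 with an estimated correlation, range over the alternatives 0.00618 to 0.496). Of its 17 genes, 9 were also in another list. Cholesterol synthesis and uptake passed as lower with 2 of 21 genes down, DHCR7 (-1.27, adjusted p = 0.0280) and SQLE (-1.41, adjusted p = 0.0432), and 1 up and 5 down adjusted over the list alone (median -0.24, camera's adjusted p = 0.0426, adjusted p = 0.304 with an estimated correlation). Over the alternatives the list's adjusted p ranged from 0.0102, given by fry, to 0.304, given by camera with an estimated correlation. Oxidative phosphorylation passed as lower with none of 29 genes called in either adjustment (median -0.17, camera's adjusted p = 0.0426, adjusted p = 0.666 with an estimated correlation, range over the alternatives 0.00656 to 0.666). These granulosa, steroid and lipid genes were measured on WSD+T arrays whose myeloid scores were 1.00, 0.72 and 0.92 and whose GAPDH 3'/5' ratio, a sign of RNA quality, was 1.63 ± 0.10 against 1.41 ± 0.13 in control.

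Insulin and IGF signalling passed as higher with 1 of 33 genes up, SHC1 (0.70, adjusted p = 0.0322), and 2 up adjusted over the list alone (median 0.16, camera's adjusted p = 0.00916, adjusted p = 0.198 with an estimated correlation). Over the alternatives the list's adjusted p ranged from 0.000560, given by fry, to 0.198, given by camera with an estimated correlation. Smooth muscle and pericyte markers were higher as a list, with none of 7 genes called over all genes and 2 adjusted over the list alone (median 0.41, camera's adjusted p = 0.00726, adjusted p = 0.304 with an estimated correlation, range over the alternatives 0.00247 to 0.304). Oocyte genes passed as higher with 1 of 15 called in either adjustment, the oocyte transcription factor FIGLA (1.93, adjusted p = 0.0380) (median 0.66, camera's adjusted p = 0.00719, adjusted p = 0.615 with an estimated correlation, range over the alternatives 0.000160 to 0.615). Ovulatory response genes passed as higher with none of 18 called over all genes and 1 adjusted over the list alone (median 0.59, camera's adjusted p = 0.0103, adjusted p = 0.496 with an estimated correlation, range over the alternatives 0.000167 to 0.496).

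Among lists of other cells, macrophage and myeloid markers had a median of 1.95, with none of 13 genes called in either adjustment (camera's adjusted p = 0.00207, adjusted p = 0.615 with an estimated correlation, range over the alternatives 2.76e-06 to 0.864). The lysozyme gene LYZ was 1049.9 ± 1187 in control and 3994 ± 129 in WSD+T (adjusted p = 0.252). Endothelial markers (median 0.82, camera's adjusted p = 0.00719, adjusted p = 0.615 with an estimated correlation, range over the alternatives 0.00136 to 0.864) had none of 9 genes called over all genes and 1 adjusted over the list alone. Lymphocyte markers (median 0.98, camera's adjusted p = 0.0386, adjusted p = 0.496 with an estimated correlation, range over the alternatives 0.0192 to 0.496), the interferon response (median 0.41, camera's adjusted p = 0.00662, adjusted p = 0.615 with an estimated correlation, range over the alternatives 0.00117 to 0.864) and inflammatory cytokines and NF-kB (median 0.46, camera's adjusted p = 0.0314, adjusted p = 0.666 with an estimated correlation, range over the alternatives 0.00385 to 0.723) passed as higher with no gene called in either adjustment. The myeloid scores of WSD+T, given with the granulosa genes, lay above 0.16, -1.62 and -1.46 on the 3 control arrays. With that score as a covariate these 5 lists had adjusted p from 0.276 to 0.864, the ovulatory list 0.182, the oocyte list 0.377, the granulosa list 0.163 and oxidative phosphorylation 0.0533, and the inflammatory list's median turned to -0.22. The loss of the macrophage and myeloid list was fixed in advance, since the covariate is its own mean.

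Control replicate 3 decided the calls of 6 lists. Without it, steroidogenesis, granulosa cells, oocyte, lymphocytes, cholesterol and oxidative phosphorylation had adjusted p = 0.0919, 0.0582, 0.0665, 0.118, 0.0919 and 0.550. Without control replicate 2, ovulatory response, inflammatory, lymphocyte and cholesterol genes had 0.0539, 0.454, 0.0683 and 0.0709. The cholesterol list also did not pass without WSD replicate 1 (0.0556), WSD replicate 3 (0.0603), WSD+T replicate 2 (0.0538) or WSD+T replicate 3 (0.0756). Oxidative phosphorylation did not pass without WSD replicate 1 (0.0556), WSD replicate 2 (0.0532), WSD+T replicate 2 (0.0534) or WSD+T replicate 3 (0.0756), and the inflammatory list had 0.0574 without WSD+T replicate 3. Without a filter on dim probe sets, steroidogenesis, inflammatory genes and lymphocytes had 0.104, 0.0951 and 0.182. The cholesterol list had 0.0653 under quantile normalization and 0.0909 under median centring, and oxidative phosphorylation 0.112 under quantile normalization and 0.0845 under cyclic loess.

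The 18 lists that did not pass had camera adjusted p from 0.143 to 0.965. In lipid storage, FADS2 fell (-1.19), and the list's median of 0.05 and camera's direction, down, differed in sign (adjusted p = 0.547). CENPN fell (-1.16) among androgen-induced genes (adjusted p = 0.305), and the unfolded protein response had a median of 0.00 with no gene called (adjusted p = 0.965). Median, mean and direction also differed in sign for hormone receptors, antioxidant defence and the TGF-beta family.

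In limma, 520 probe sets passed (143 higher, 377 lower), or 305 genes, and 372 changed at least 2-fold. The lower share of 72.5% fell to 44.7% in a fit to the 6 control and WSD+T arrays alone (1796 higher, 1449 lower of 3245), 46.7% without WSD replicate 3 (948 and 829), 48.3% with weights per group (1690 and 1577) and 45.0% with gene-by-gene weights (2506 and 2049). Groups did not overlap in 9716 of the tested probe sets (36.8%, against 10% by chance) and in all 520 called. The main fit gave all groups 1 spread per probe set, although the mean within-group variance was 0.330 in WSD, 0.152 in control and 0.0411 in WSD+T. The count thus depended on the WSD arrays, which are not in this comparison, as well as on its own arrays. It was 0 without WSD+T replicate 1 (3006 probe sets at an unadjusted p under 0.05) and 0 without WSD+T replicate 3 (3151), where HSD3B2 had adjusted p = 0.101 (range over the leave-one-out fits 0.00335 to 0.101). It was 123 without WSD+T replicate 2, 224, 97 and 104 without control replicates 1, 2 and 3, 1595 without WSD replicate 2 and 1777 without WSD replicate 3. With the GAPDH ratio as a covariate it was 11, and with WSD+T replicates 1 and 3, the most alike of all arrays, averaged into 1 sample, it was 0. Of the 24 genes with the largest changes, 13 passed without WSD replicate 1, 9 without WSD+T replicate 2, 16 without control replicate 1, and 7 without control replicate 2 or 3.

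The comparison of WSD+T with WSD asks what testosterone added to the diet. It shares the WSD arrays with the comparison of WSD and control, so chance values of these arrays enter both with opposite signs. Several genes called in WSD vs control were called here in the other direction: NFATC2 fell from 2045 ± 461 to 227 ± 141 (log2 fold change -3.21, SE 0.40, adjusted p = 0.0166), CHAC1 fell (-2.81), and LUM rose from 21.5 ± 11.3 to 273 ± 137. The glutamate dehydrogenase GLUD1 fell from 1280.2 ± 254 to 248 ± 35.5 (-2.29, SE 0.24, adjusted p = 0.0146) and the water and glycerol channel AQP3 from 1158 ± 169 to 231 ± 92.5. OSM rose from 3.10 ± 2.02 to 121 ± 30.0 and TNC from 63.2 ± 17.3 to 421 ± 100.1. HSD3B2 fell further (-1.21, SE 0.16, adjusted p = 0.0182).

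Other increases were in the G-protein regulator RGS1 (3.03, SE 0.53, adjusted p = 0.0312), the matrix proteases ADAMTS18 (2.66) and ADAMTS5 (1.98), LIN7A (2.61), TDO2 (2.57), the homeobox gene HOXA3 (2.39), NLRP14 (2.14), THAP2 (1.89, SE 0.16, adjusted p = 0.0136) and NHLH2 (1.86). Decreases were found in CA13 (-2.56), MLF1 (-2.12), TNFAIP6 (-2.07), the oestrogen-metabolising enzyme CYP1B1 (-1.93), the immediate early gene ARC (-1.68) and the aggrecanase ADAMTS4 (-1.62). OSM, THAP2 and NHLH2 had mean signals under 21.2 in WSD, and their fold changes depend on the pseudocount. SNX17 (-2.23) and ZNF655 (-1.99) fell on 1 probe set each, and the other tested probe set of each went the opposite way.

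The unfolded protein response list was lower in WSD+T than in WSD, with 1 of 18 genes down, CHAC1, none up and 17 not past the threshold, and 1 up and 5 down adjusted over the list alone (median -0.33; camera's adjusted p = 0.000161, adjusted p = 0.532 with an estimated correlation, range over the alternatives 3.27e-06 to 0.532). CHAC1 passed in 1 of 9 fits without 1 array, that without WSD replicate 2 (highest adjusted p of the fits 0.169, lowest 0.0246). The list's score was -0.20 ± 0.07 in control, 0.36 ± 0.17 in WSD and -0.16 ± 0.13 in WSD+T. Members next in order were EDEM1 (0.51, adjusted p = 0.0654), XBP1 (-0.62, adjusted p = 0.0709) and HERPUD1 (-0.86, adjusted p = 0.0832). Glycolysis passed as lower with 1 of 18 genes down in either adjustment, the enolase ENO2 (-0.57, adjusted p = 0.0490) (median -0.23, camera's adjusted p = 0.00295, adjusted p = 0.353 with an estimated correlation, range over the alternatives 0.000331 to 0.353), and it had adjusted p = 0.0711 under cyclic loess. The phosphofructokinase PFKP was -0.74 (adjusted p = 0.180).

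No other list passed, with camera adjusted p from 0.116 to 0.913. The count of 2 lists, none higher, was 9 without WSD replicate 2 (5 higher, 4 lower), 5 without WSD replicate 3 and 7 with the GAPDH ratio as a covariate (2 higher, 5 lower). Called members included HSD3B2, given above, AREG, which fell from 159 ± 41.5 to 54.0 ± 19.2 (adjusted p = 0.0472), DIABLO (-0.56), the mTOR inhibitor TSC1 (1.01), the activin receptor ACVR1B (1.26), the BMP target ID3 (1.06), the chaperone HSPH1 (0.71) and the extracellular matrix genes LUM, TNC and ADAMTS5, all higher, and ADAMTS4, lower. Androgen-induced genes had no member called (adjusted p = 0.285), with FKBP5 at -0.66 (adjusted p = 0.212) and TMPRSS2 at 0.53 (adjusted p = 0.446). Proliferation had a median of -0.04 with none of 24 genes called (adjusted p = 0.159). CYP19A1 was -1.87 (adjusted p = 0.0924) and CYP17A1 0.76 (adjusted p = 0.145). The myeloid markers had a median of 0.81 (adjusted p = 0.550), and their score was -2.27 on WSD replicate 3, 0.82 and 1.73 on WSD replicates 1 and 2, and 0.72 to 1.00 in WSD+T. Among the lists that did not pass, median, mean and camera's direction differed in sign for steroidogenesis, hormone receptors, androgen-induced genes, insulin and IGF signalling, fatty acid oxidation, lipid storage, inflammatory and interferon genes, ribosomal proteins, the circadian clock and granulosa cells.

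In limma, 789 probe sets passed (539 higher, 250 lower), or 420 genes, 1 of them with probe sets in both directions, and 411 probe sets changed at least 2-fold. The lower share was 31.7%, and it was 51.7% under quantile normalization (303 higher, 324 lower), 64.9% under median centring (204 and 377) and 57.0% under cyclic loess (287 and 381). Groups did not overlap in 7516 tested probe sets (28.5%, against 10% by chance) and in all 789 called. The count was 0 without WSD+T replicate 1 (3782 at an unadjusted p under 0.05), 0 without WSD+T replicate 2 (3712), 2 without WSD+T replicate 3 and 45 without WSD replicate 1, and a fit to the 6 arrays alone called 9. It was 1548 without WSD replicate 2, 1488 without WSD replicate 3 and 404, 494 and 479 without control replicates 1, 2 and 3, 102 with the GAPDH ratio as a covariate, and 0 with WSD+T replicates 1 and 3 averaged. Of the 24 genes with the largest changes, 4 passed without WSD replicate 1, 15 without control replicate 3, 2 without WSD+T replicate 3 and none without WSD+T replicate 1 or 2, where NFATC2 had adjusted p up to 0.122 (lowest of the leave-one-out fits 0.0170).

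**Figure D2:**
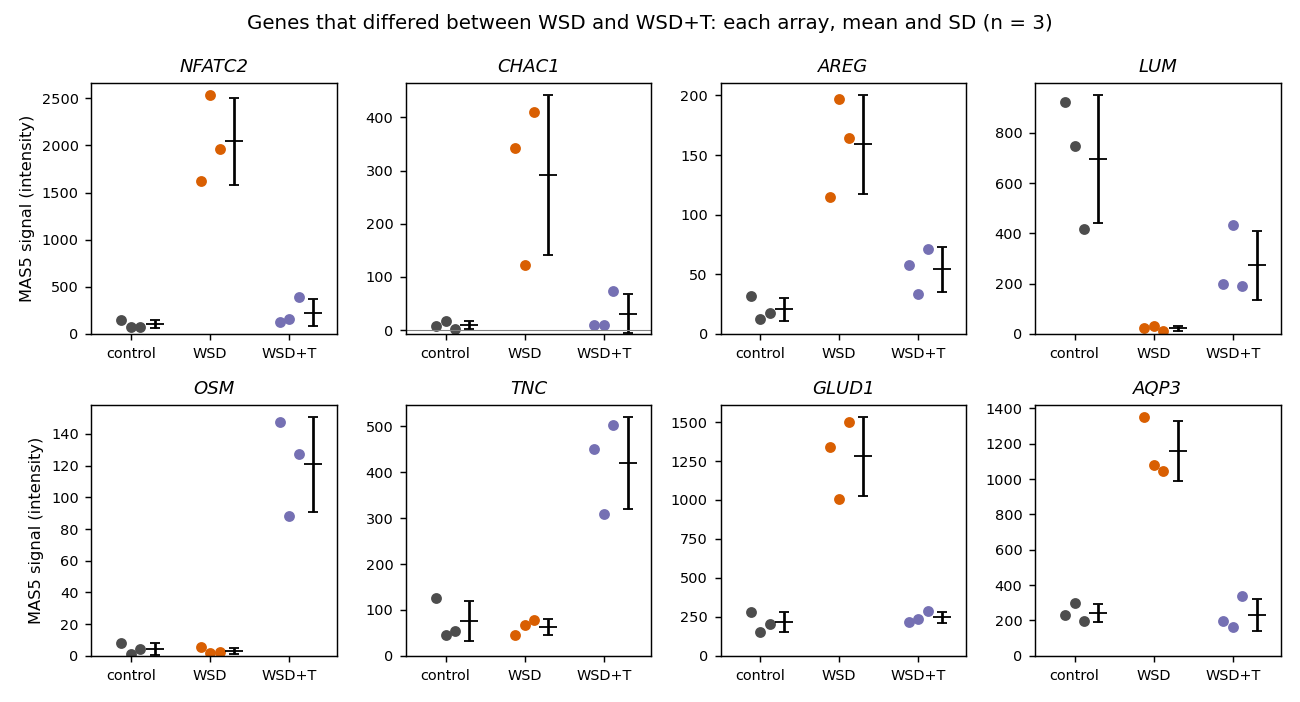
Signal (MAS5 intensity, linear axis) of 8 genes with large changes between WSD and control or between WSD+T and WSD, on the 9 arrays, by group. Points are single arrays and bars show the group mean ± SD: GLUD1 was 215 ± 64.6 in control, 1280.2 ± 254 in WSD and 248 ± 35.5 in WSD+T, and OSM was 4.42 ± 3.66, 3.10 ± 2.02 and 121 ± 30.0.

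Across the 3 groups, limma's F test called 3097 probe sets (8102 at an unadjusted p under 0.05), and 4115 were called in at least 1 pairwise comparison. The F count was 5871 without WSD replicate 3, 1656 without WSD replicate 1, 1828, 1287 and 1370 without control replicates 1, 2 and 3, and 873, 1398 and 1079 without WSD+T replicates 1, 2 and 3, and 1028 with WSD+T replicates 1 and 3 averaged. Among genes fixed beforehand, the anti-Müllerian hormone gene AMH, a product of growing follicles, was 315 ± 81.0 in control, 160.3 ± 69.7 in WSD and 120.3 ± 38.0 in WSD+T (adjusted p = 0.104 and 0.109 against control). The cholesterol transporter STAR was 2513 ± 573, 3193 ± 839 and 2384 ± 77.4 (adjusted p = 0.349, 0.938 and 0.392). Of the oestrogen receptors, ESR1 lay under the filter and neither tested probe set of ESR2 passed. FSHR, LHCGR and INSR had no probe set under those names in the annotation used and were not analysed here.

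The comparisons with control share the control arrays, which links their ranks by p. Of the probe sets called in both, 69 were higher in both, against 6.84 for independent calls and 73.3 (range 66 to 88) in simulations. The latter took as many probe sets by smallest p in 20 simulated data sets with no change in any group. They are matched in rank only, since past the threshold these data sets had 0.15, 0 and 0 calls on average in the 3 comparisons. Lower in both were 321, against 36.5 and 213.9 (range 196 to 229), and 1 had opposite directions. The count higher in both lay in the simulated range, and part of the excess lower in both may come from the shared controls, whose 3 arrays cannot be divided into sets of at least 2. The genes MKI67, TPX2, MCM3, MCM2, INHA, INHBB, IHH and HSD3B2 were among those lower in both. The fold changes had a covariance of 0.263 over all tested probe sets, against 0.0584 in simulations where only the shared control arrays linked them, a difference of 0.204. Pearson's r across probe sets, which are not independent replicates, was 0.719 against 0.501 simulated, and 72.9% of probe sets had the same sign against 66.7% simulated. The simulated probe sets varied independently, whereas in the data 47.3% of the variance lay on the first principal component. With probe sets that vary together, the shared control arrays could give values further from the simulated ones. The excess in covariance, r and sign therefore does not show a shared effect. The covariance was 0.184 without WSD replicate 2 and 0.346 and 0.374 without WSD replicate 3 and control replicate 1. Between WSD vs control and WSD+T vs WSD, which share the WSD arrays, 189 probe sets were higher in the first and lower in the second, against 115.25 (range 98 to 128) in the same simulations, and 387 lower and then higher, against 292 (range 272 to 311). Both counts were above the simulated ranges, which assumed the same spread in every group. Between WSD+T vs control and WSD+T vs WSD, which share the WSD+T arrays, the overlap in 1 direction was below them, with 30 higher in both against 53.95 (range 46 to 64) and 15 lower in both against 65.4 (range 53 to 80). In opposite directions it was above them: 2 were higher and then lower, against 0.35 (range 0 to 1), and 8 lower and then higher, against 2.15 (range 0 to 5). In the data, the mean within-group variance was 0.330 in WSD, 0.152 in control and 0.0411 in WSD+T. The overlap that a shared group alone would give depends on these variances. Counts outside the simulated ranges therefore do not show shared or opposed effects.

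**Figure D3:**
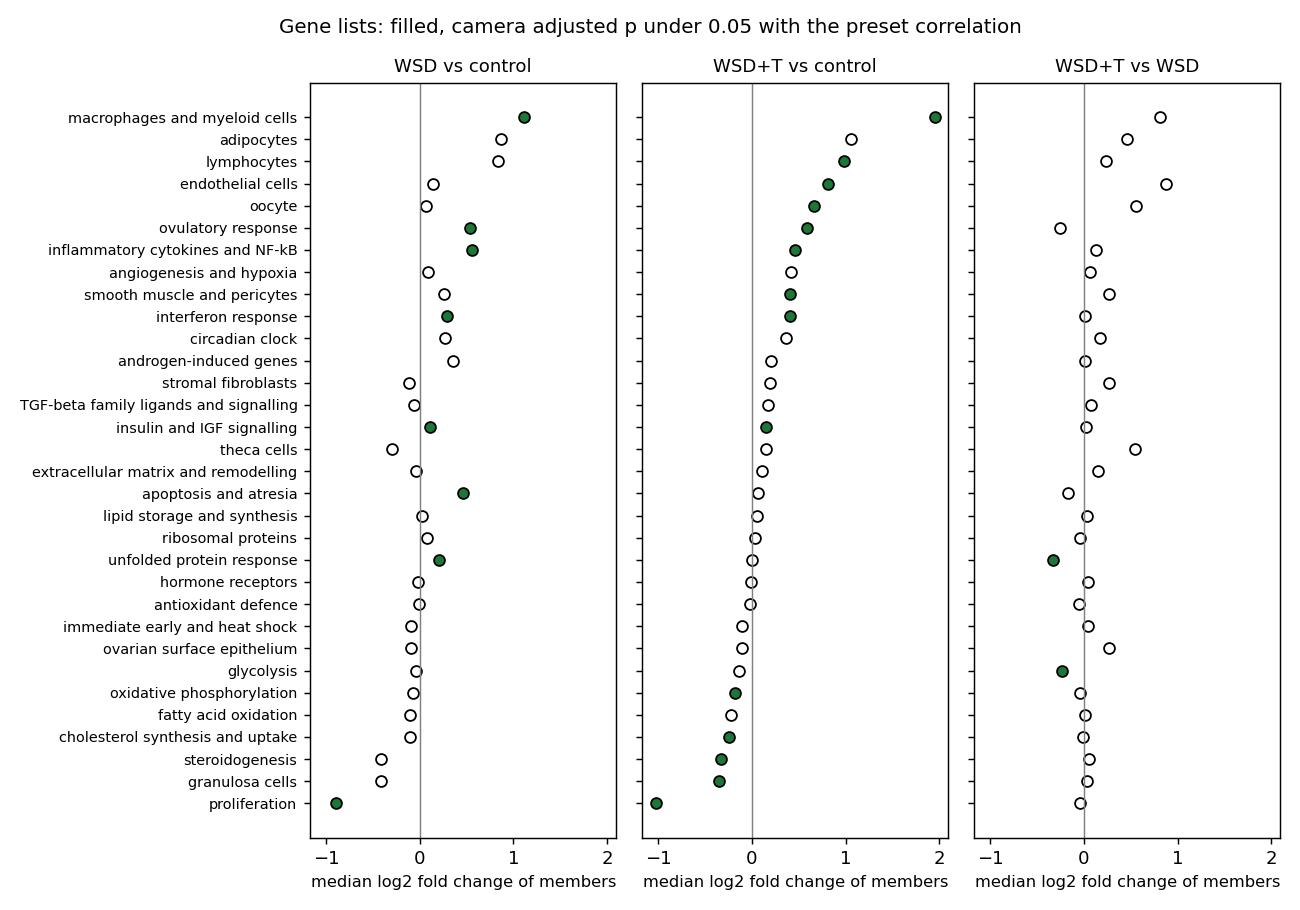
Median log2 fold change (x axis) of the tested genes of each of 32 lists (y axis) in the 3 comparisons. Filled points passed camera's threshold with the preset correlation, 8, 14 and 2 lists in turn, and no list passed with an estimated correlation.

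**Figure D4:**
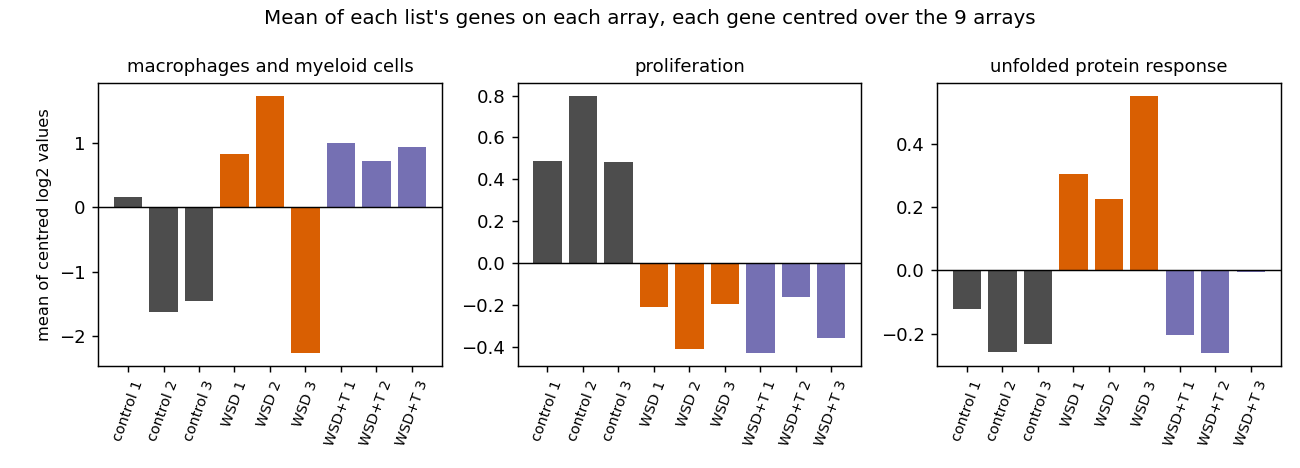
Mean of the centred log2 values (y axis) of macrophage and myeloid, proliferation and unfolded protein response genes on each of the 9 arrays (x axis, bars). Myeloid scores were 0.82 and 1.73 on WSD replicates 1 and 2 and -2.27 on WSD replicate 3, and proliferation scores were at least 0.48 in control and at most -0.16 in the other groups.

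The groups also differed in the spread among their arrays. The mean within-group variance was 0.152 in control, 0.330 in WSD and 0.0411 in WSD+T, on the squared log2 scale. WSD replicates 2 and 3 held 24.8% and 30.4% of the residual sum of squares, and WSD+T replicates 1 and 3 held 2.00% and 2.04%. The first principal component, with 47.3% of the variance, had WSD replicate 2 at -95.7 and control replicate 2 at 73.7 as its ends. The β-actin 3'/5' ratio was 2.75 ± 0.20 in control, 2.71 ± 0.44 in WSD and 2.71 ± 0.24 in WSD+T, and the GAPDH ratio in WSD was 1.53 ± 0.07.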

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

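The tests of cell cycle genes with the myeloid marker score, of both lists with the 3'/5' ratios, of the unfolded protein response without single WSD arrays, of the spread with the myeloid score and of a shared RNA behind WSD+T replicates 1 and 3 were chosen after the result was seen. The difference between the effects of WSD and of WSD+T against control was tested directly for each list as WSD+T vs WSD with camera. It passed for the unfolded protein response (adjusted p = 0.000161) and for glycolysis (adjusted p = 0.00295), and neither passed with an estimated correlation (adjusted p = 0.532 and 0.353). Their ranges over the alternatives stand with the comparison of WSD+T and WSD.

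The cell cycle list passed camera as lower in both WSD and WSD+T than in control, with 15 and 11 of 24 genes called. The tables argue against more RNA from myeloid cells as the whole cause: with the myeloid score as a covariate, camera's larger adjusted p over the comparisons with control was 1.00e-06, and the medians were -0.83 and -0.83, against -0.89 and -1.02 without it. These p values hold at the preset correlation only, since with an estimated correlation the list had adjusted p = 0.446 in WSD and 0.198 in WSD+T, without the covariate. RNA quality, as read by the actin and GAPDH 3'/5' ratios, did not remove it either (largest adjusted p = 2.07e-06). A change in the granulosa cells' division, in the mix of follicle stages pooled or in other cell types may still underlie it, and diet and testosterone stay open as untested causes.

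The unfolded protein response list passed camera as higher in WSD than in control, with 4 of 18 genes up and 1 down, and lower in WSD+T than in WSD, with CHAC1 as its only called gene of 18 (past the threshold in 1 of 9 fits without 1 array), in comparisons that share the WSD arrays (adjusted p = 0.529 and 0.532 with an estimated correlation). In WSD+T vs WSD another of the 10 splits gave a smaller unadjusted camera p (4.94e-06 against 5.03e-06). At camera's preset correlation the list passed in both comparisons whichever WSD array was left out, with a largest adjusted p of 0.0416, close to the threshold. This test was chosen after the result was seen, and the list did not pass with an estimated correlation. It thus cannot exclude that a single WSD array contributed. With the 3'/5' ratios as covariates the largest adjusted p was 0.0170, which argues against RNA quality as the whole cause. Handling of the follicles before lysis was not recorded in the labels and could not be tested, and an effect of the diet that testosterone offset may be considered only as a hypothesis, untested here.

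The WSD+T arrays spread less than the WSD arrays, with a variance ratio of 8.03. With the myeloid score in the fit the ratio fell to 2.01, just over a bound of 2 set beforehand. Leaving out each of 13 markers in turn, a spread added after the value was seen, gave 1.95 to 2.06. Part of this fall was fixed in advance, since the score varied most among the WSD arrays (SD 2.09, against 0.98 in control and 0.14 in WSD+T). Any covariate that varies mainly there takes up WSD variance, and the ratio was not corrected for this. The ratio thus cannot tell how much of the difference a different myeloid share between arrays accounts for, and that explanation stays open. WSD+T replicates 1 and 3 differed by an SD of 0.119 over 7539 bright probe sets, with 3 of these over 2-fold apart, against 148 to 238 in control pairs and 14 and 17 in the other WSD+T pairs. The correlation between probe sets of a gene in their difference was 0.190 (interval 0.149 to 0.231). Repeated hybridisation of 1 labelled target was assumed to leave no such correlation, which was not checked, and separate labelling of 1 RNA allows any. The value thus cannot exclude either. The labels call WSD+T replicates 1 and 3 biological replicates, pooled by female and ovary, so 2 ovaries of 1 female are also possible, which would leave 2 females in WSD+T.

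Splits of the samples bear on chance. In each pairwise comparison 10 splits of the 6 arrays are too few for a share under 0.05. The real count of probe sets was 3817 against 651 in the highest other split for WSD vs control, 520 against 0 for WSD+T vs control and 789 against 0 for WSD+T vs WSD, so that 1 split, the real one, gave as many in each. For lists, the real count was 8 against 13, 14 against 15 and 2 against 8, and 3, 3 and 10 of 10 splits gave as many. Single called lists differed. Oxidative phosphorylation in WSD+T vs control had a camera p as small in 8 of 10 splits, the real one included. In WSD vs control the myeloid list had it in 6 and the inflammatory list in 5. Proliferation and insulin and IGF signalling had it in the real split only, in both comparisons with control. For the F test, 1 of 100 drawn splits, the real one, gave 3097 probe sets and the highest other gave 756. This argues against chance at 0.05 only if the 9 arrays are independent, which WSD+T replicates 1 and 3 may not be. With these averaged the F count was 1028, which was not set against splits. Splits also cannot separate diet or testosterone from any other difference between the groups.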

How the results depend on the processing

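Array weights per group and gene by gene, the average of WSD+T replicates 1 and 3, the myeloid score, and the 3'/5' ratios for lists were alternatives chosen after seeing the data. All 84 named genes that passed in WSD vs control kept their direction in every alternative where they were tested, and 33 also stayed past the threshold in each. The 36 in WSD+T vs control and 33 in WSD+T vs WSD kept direction too, and none stayed past the threshold in all. Of called lists, 3 of 8, 3 of 14 and 0 of 2 stayed past it in every alternative except the estimated correlation. One called list changed direction: inflammatory cytokines and NF-kB in WSD+T vs control had a median of -0.22 with the myeloid score (adjusted p = 0.723, range over its alternatives 0.00385 to 0.723). Unless stated, the cause was not tested.

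Counts of probe sets are given for WSD vs control (3817), WSD+T vs control (520), WSD+T vs WSD (789) and the F test (3097). Leaving out 1 array gave 1735 to 6628, 0 to 1777, 0 to 1548 and 873 to 5871. Array weights by REML gave 11193, 4746, 15595 and 17987, but 1 array dominated this estimate (weight 34.1 for WSD replicate 1, with WSD+T replicate 1 next at 2.85). Gene-by-gene weights gave 6908, 4555, 8071 and 10976. Weights per group gave 1367, 3267 and 186 in the pairwise comparisons. Fits to the arrays of 2 groups only gave 913, 3245 and 9, with fewer samples and each pair's own spread. With weights per group and with these fits, WSD+T vs control had the most calls of the pairwise comparisons, whereas WSD vs control had in the main fit. The counts therefore do not rank the sizes of the effects. One probe set per gene gave 1766, 324, 355 and 1480, as fewer were tested. Averaging WSD+T replicates 1 and 3 gave 2536, 0 (3072 at an unadjusted p under 0.05), 0 (3956) and 1028, with 1 sample fewer. The upper-quartile filter gave 2398 in WSD vs control, with fewer probe sets tested. Actin's ratio as a covariate gave 1187 in WSD+T vs control and 1308 in WSD+T vs WSD, and GAPDH's 11 and 102. The myeloid score gave 2376 in WSD+T vs WSD and 4719 in the F test. The replicate block as a fixed effect gave 2220, 3, 1 and 978, and as a random effect 406 in WSD+T vs WSD. No pairing by replicate number was seen: residual correlations of the 9 pairs with 1 number ran from -0.302 to 0.190, with 4 over 0.1, and the consensus correlation was -0.0872. Pairs with different numbers ran from -0.446 to 0.427, so this check cannot exclude that the numbers mark a shared day or batch.

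List counts were 8, 14 and 2 in the pairwise comparisons in turn, and 4 to 8, 9 to 13 and 2 to 9 without 1 array. An estimated correlation left 0, 0 and 0 (2, 5 and 3 lists at an unadjusted p under 0.05), and fry called 5, 5 and 0 (9, 9 and 5 unadjusted). The myeloid score left 4 and 6 in the comparisons with control. In WSD+T vs WSD, no filter gave 6, median centring 4, cyclic loess 1, GAPDH's ratio 7 and the mean of a gene's probe sets 4. The covariance of 0.263 between the comparisons with control was 0.366 with a pseudocount of 1, 0.155 with 64, 0.151 without a filter, and 0.184 to 0.374 without 1 array. Signal over background limits the genes near the filter's signal of 21.2, such as OSM, which lay under it whenever 1 WSD+T array was left out. Small changes were also limited: 0 to 2 of 50 simulated changes of 1.5-fold were recovered per comparison, with an equal spread in all simulated groups.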

Other observations

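The tests in this part were chosen before any result was seen. Lists of further functions and cell types, with no call by camera in WSD vs control, held genes that changed after WSD. Of all tested probe sets 14.5% were called in that comparison, and 1766 of 10002 genes with 1 probe set per gene. A few called genes in a list are therefore no sign that its function or cell type changed. The clock genes CRY2, a repressor, and RORA, an activator, moved apart (-1.23 and 1.88, adjusted p = 0.00777 and 0.00903, limma), in a circadian list with a median of 0.27 (camera's adjusted p = 0.308). In the theca list 2 of 10 genes fell after WSD, CYP17A1 and PTCH1 (-1.67 and -1.96, camera's adjusted p = 0.511). Among ovarian surface epithelium markers the transcription factor LHX9 fell (adjusted p = 0.00802) and the keratin KRT8 rose (1.64, camera's adjusted p = 0.773). The zona pellucida gene ZP4 rose (1.04) and NLRP7 fell (-0.62) among 15 oocyte genes (camera's adjusted p = 0.511). The adipokine ADIPOQ fell (-0.71, adjusted p = 0.0291) in an adipocyte list with camera's adjusted p = 0.864, the ribosomal protein gene RPS10 fell (-0.48), the complex I subunit NDUFS7 fell (-0.98), and the peroxisomal enzyme EHHADH fell (-0.66).

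Among red blood cell genes, of which 3 were tested and too few for a list test, HBA fell after WSD (-0.53, adjusted p = 0.0310). HBB, the haemoglobin beta chain, fell in WSD+T against control (-1.36, SE 0.20, adjusted p = 0.0218) and against WSD (-1.20, adjusted p = 0.0303). The stromal fibroblast list had LUM as its only called gene in WSD vs control and in WSD+T vs WSD (camera's adjusted p = 0.864 and 0.173).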
